A study of Mus musculus with 4 samples.

How the data were processed

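Polyadenylated RNA was sequenced from 4 cultures of RAW 264.7 cells, a mouse macrophage cell line, of wild-type or Hnrnpul1-/- genotype, untreated or given lipopolysaccharide (LPS, a bacterial cell wall component sensed by TLR4) at 100 ng/ml for 10 h. Each of the 4 groups held 1 library. Per the labels' protocols, mRNA was captured on poly-T beads and cDNA was primed with random hexamers. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the builds GRCm38 and mm10; whether the counting used strand is not given in the sources used here. The deposited read counts are whole numbers per gene, not normalized, for 54532 genes. The deposited FPKM values equal the count divided by gene length and by a constant per library. These constants were 1.15, 1.16, 0.932 and 0.927 times the total counts of untreated wild type, untreated knockout, LPS-treated wild type and LPS-treated knockout, so the deposited FPKM carry a composition scaling of their own. Gene symbols, coordinates and biotypes were taken from the deposited count tables.

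Total counts were 17162124 in untreated wild type, 17361615 in untreated knockout, 17045432 in LPS-treated wild type and 17909549 in LPS-treated knockout. A floor of 3 counts corresponded to 0.158, 0.155, 0.195 and 0.186 normalized CPM, the unit edgeR gives for counts scaled by library size, in these libraries. TMM factors (edgeR 4.0.16 in R 4.3.3) were computed over genes with a mean CPM of at least 1 and were 1.11, 1.12, 0.901 and 0.899. The filter left 11640 genes, of which 10334 were protein-coding.

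Each comparison was the log2 ratio of TMM-normalized counts of a pair of libraries, with an exact conditional (Clopper-Pearson) 95% interval. With 1 library per group there is no replicate check: the intervals cover counting error only, reads without molecular identifiers are not independent molecules, and a difference between libraries is not tested as a difference between conditions. A gene was called higher or lower when its ratio was at least 2-fold and its interval excluded no change. A count of 0 entered a ratio as 3 counts per library. Such a ratio depends on this floor, and its counting limit, which can lie nearer to no change, gives the bound. Counts of 1 or more were left as they were, so a count of 0 ranked above a count of 1. The direction could thus be reversed: Lif, with 1 read in untreated wild type and 0 in untreated knockout, took a log2 ratio of 1.56. These ratios entered the list medians, the counts of members above 0 and the correlations. The interaction was the LPS log2 ratio in knockout minus that in wild type, with a delta-method interval. Calls of the same contrast in its 2 pairs of libraries, which share no library, were set beside the overlap of independent lists.

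Before the data were examined, 34 gene lists were fixed. For each, the median log2 ratio was given with its percentile among 10000 random lists of the same size, as a description of these libraries. The random lists were matched on mean expression over the 4 libraries in 20 bins. LPS-induced genes with few untreated reads were thus set against genes with more, whose ratios vary less by counting. Percentiles of such lists untreated or in the interaction do not allow for this. The 5 measured members required were present in 27 lists. Medians outside the central 95% of random lists were read as standing apart, which 1.35 of 27 lists would do by chance in a comparison. Named genes followed a rule also set in advance. It took Hnrnpul1, 12 fixed LPS response genes and up to 4 members of each list with the largest absolute ratio. Among protein-coding genes with a mean CPM of at least 5, it added the 6 highest and 6 lowest called in both pairs of a contrast or in the interaction, and up to 4 per direction called in 1 genotype comparison and not in the other.

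The calling rule was tested on simulated libraries of 11640 genes with 200 changed genes. In the untreated genotype comparison, 18 unchanged genes were called at counting noise alone, 42 at an assumed biological coefficient of variation of 0.1 and 304 at 0.2; in the LPS-treated one these numbers were 32, 54 and 315. In the wild-type LPS comparison they were 23, 35 and 288, in the knockout LPS comparison 22, 43 and 319, and in the interaction 56, 120 and 1188. The interaction simulation gave unchanged genes the same mean level in every library, without an LPS effect. At counting noise alone, 98% of genes changed 3-fold were recovered in the untreated genotype comparison.

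Alternatives were DESeq2 1.42.0 size factors, total counts, no filter, a mean CPM of at least 10, a 1.5-fold rule, the whole interval beyond 2-fold, protein-coding genes alone, libraries thinned to 17045432 counts, and the deposited FPKM as log2(value + 1) with a mean of at least 1. The FPKM calls used the 2-fold size alone, without a counting interval, so both their rule and their set of genes differ. An additive genotype and LPS model was fitted with edgeR's quasi-likelihood test; it has 1 residual degree of freedom, so that its error term is the interaction itself. Restricting list members to those with a mean of at least 10 reads was chosen after seeing the data. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.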

Results

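The data comprised 4 RNA-seq libraries of RAW 264.7 mouse macrophage cells, 1 each for untreated wild type, untreated Hnrnpul1-/-, LPS-treated wild type and LPS-treated Hnrnpul1-/- (100 ng/ml, 10 h). Total counts ranged from 17045432 to 17909549. Levels are TMM-normalized CPM and differences are log2 ratios with 95% counting intervals, which cover counting error only; no value has a replicate. The comparisons ask what LPS did in each genotype, what the loss of Hnrnpul1 did with and without LPS, and whether the LPS response differed between genotypes.

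Hnrnpul1 encodes an RNA-binding protein of the hnRNP U-like group and lies on chromosome 7 from 25721165 to 25754757 (GRCm38, minus strand; ENSMUSG00000040725). Its level was 268 CPM in untreated wild type and 23.1 CPM in untreated knockout, so that 8.62% remained (7.81 to 9.50%). Under LPS, Hnrnpul1 stood at 203 CPM in wild type and 21.7 CPM in knockout, a remainder of 10.7% (9.57 to 11.97%). The read counts of Hnrnpul1 were 5086, 447, 3114 and 350 in untreated wild type, untreated knockout, LPS-treated wild type and LPS-treated knockout. The genotype labels of all 4 libraries were thus matched by the targeted transcript, of which some reads remained. Of 18 measured genes within 500 kb of Hnrnpul1, only the pseudogene Rnf170-ps met the size rule between genotypes, with a log2 ratio of 1.47 under LPS; its direct neighbour Axl had log2 ratios of 0.66 untreated and 0.28 under LPS.

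LPS raised inflammatory cytokine, interferon response and macrophage activation genes by large factors in both genotypes and lowered genes of cell division. Csf3, the granulocyte colony-stimulating factor, went from 1 read to 951 CPM in wild type (log2 ratio 14.14, 11.66 to 19.44) and from 1 read to 1424 CPM in knockout (14.75, 12.27 to 20.05). Il1b, encoding interleukin-1 beta, had 0 reads in both untreated libraries. Against the floor of 3 counts, Il1b was 1703-fold higher with LPS in wild type and 4485-fold higher in knockout. The lower counting limits were log2 ratios of 10.44 and 11.83. The prostaglandin synthase gene Ptgs2 was higher by log2 ratios of 10.16 (9.62 to 10.76) and 10.17 (9.72 to 10.66). Tnf, already at 74.2 CPM in untreated wild type and 77.8 CPM in untreated knockout, was higher by 3.99 (3.91 to 4.07) and 4.12 (4.05 to 4.20).

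Il1a (log2 ratios 10.58, 9.03 to 12.86, in wild type and 11.70, 10.15 to 13.98, in knockout), Ifi202b (11.09, 9.73 to 12.96, and 11.29, 9.74 to 13.57) and Lcn2 (9.47, 8.34 to 10.91, and 12.03, 9.55 to 17.33) completed the 6 genes with the highest mean ratio. Nos2, the inducible nitric oxide synthase, had log2 ratios of 9.02 and 9.49, and Acod1, the enzyme that makes itaconate, 9.03 and 8.71. The chemokine genes Ccl5 (9.40 and 10.19) and Cxcl10 (8.40 and 7.58), and the NF-kB feedback genes Nfkbia (2.52 and 2.71) and Tnfaip3 (2.41 and 2.70), were also higher in both genotypes. Il6, encoding interleukin-6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), had 0 reads untreated and reached 57.1 CPM in wild type and 258 CPM in knockout. Against the floor of 3 counts, Il6 was 361-fold and 1666-fold higher, with lower counting limits of log2 8.20 and 10.40. Ifnb1 had 0, 0, 12 and 9 reads and Il10 0, 0, 0 and 1 read in untreated wild type, untreated knockout, LPS-treated wild type and LPS-treated knockout, under the filter on low counts. The 6 genes with the lowest mean ratio were Klhl30 (-6.61 and -5.25), Cytip (-7.56, -12.87 to -5.07, and -3.27), Cd101, Cd24a (-4.94 and -4.84), Neurl1b (-4.99 and -4.48) and Ankle1 (-4.15 and -4.16). Cd101 went from 239 reads to 0 in wild type, 64.4-fold lower against the floor of 3 counts, and by -4.74 in knockout. Its upper counting limit in wild type was a log2 ratio of -5.70.

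All 44 measured members of the type I interferon response list were higher with LPS in both genotypes, with median log2 ratios of 6.15 in wild type and 5.92 in knockout. Of 24 cytokines and chemokines, 23 were higher in each genotype (medians 6.40 and 7.15). Of 33 macrophage activation genes listed, 25 were measured, of which 25 were higher in wild type and 24 in knockout (medians 4.42 and 3.94). Among the unmeasured, Arg1, Ido1, Cd38 and Marco had 0 to 4 reads in each library and Hp 6 to 25. NF-kB feedback genes were higher for 19 of 24 members in wild type and 20 in knockout, with Cd40 (8.51 and 7.95) and Nfkbiz (5.05 and 5.50) at the top. All 26 mitosis genes were lower in both genotypes, among them Cenpf (-3.23 and -3.40), Kif11 (-2.82 and -2.70) and Mki67 (-2.70 and -2.61), with list medians of -2.003 and -1.85. Of 33 DNA replication genes, 24 were lower in wild type and 21 in knockout (medians -1.32 and -1.19); Tk1, thymidine kinase, had ratios of -2.55 and -2.79. Double-strand break repair genes had medians of -0.93 and -1.01, with 14 and 15 of 30 members lower, such as Brca2 (-2.53 and -2.29). These lists lay at the 100th or the 0th percentile of matched random lists in both genotypes.

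Antigen presentation genes were higher for 13 of 17 members in both genotypes (medians 1.60 and 1.49), with Tap1, a peptide transporter, at 3.37 and 3.33. Glycolysis and hypoxia genes (11 of 27 higher in wild type, 12 in knockout; medians 0.82 and 0.92) and unfolded protein and stress response genes (11 of 27 higher in each; medians 0.81 and 0.77) also lay at or above the 99.9th percentile. Their leading members were Slc2a1, a glucose transporter (2.06 and 2.11), and Trib3 (3.47 and 3.62). NRF2 target genes had medians of 0.72 and 0.53, led by Hmox1, heme oxygenase 1 (5.02 and 4.16). Cholesterol synthesis genes had medians of -0.47 and -0.34, with 4 and 3 of 23 members lower.

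Across all genes, 1309 were higher and 1180 lower with LPS in wild type, and 1345 and 1398 in knockout. Genes higher in both numbered 1124 and genes lower in both 995, where independent lists would share 151 and 142; 3 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 ratios of the 2 genotypes had a Pearson correlation of 0.94. Scaling by total counts put the median of all genes at -0.30 in wild type and -0.33 in knockout, against -0.004 and -0.02 with TMM. It gave 975 higher and 1904 lower genes in wild type and 989 and 2156 in knockout. The share higher thus went from 52.6% to 33.9% and from 49.0% to 31.4%. With the deposited FPKM, called without a counting interval on another set of genes, the share higher was 59.5% in wild type (1000 higher and 681 lower) and 57.9% in knockout (1054 and 766).

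**Figure D1:**
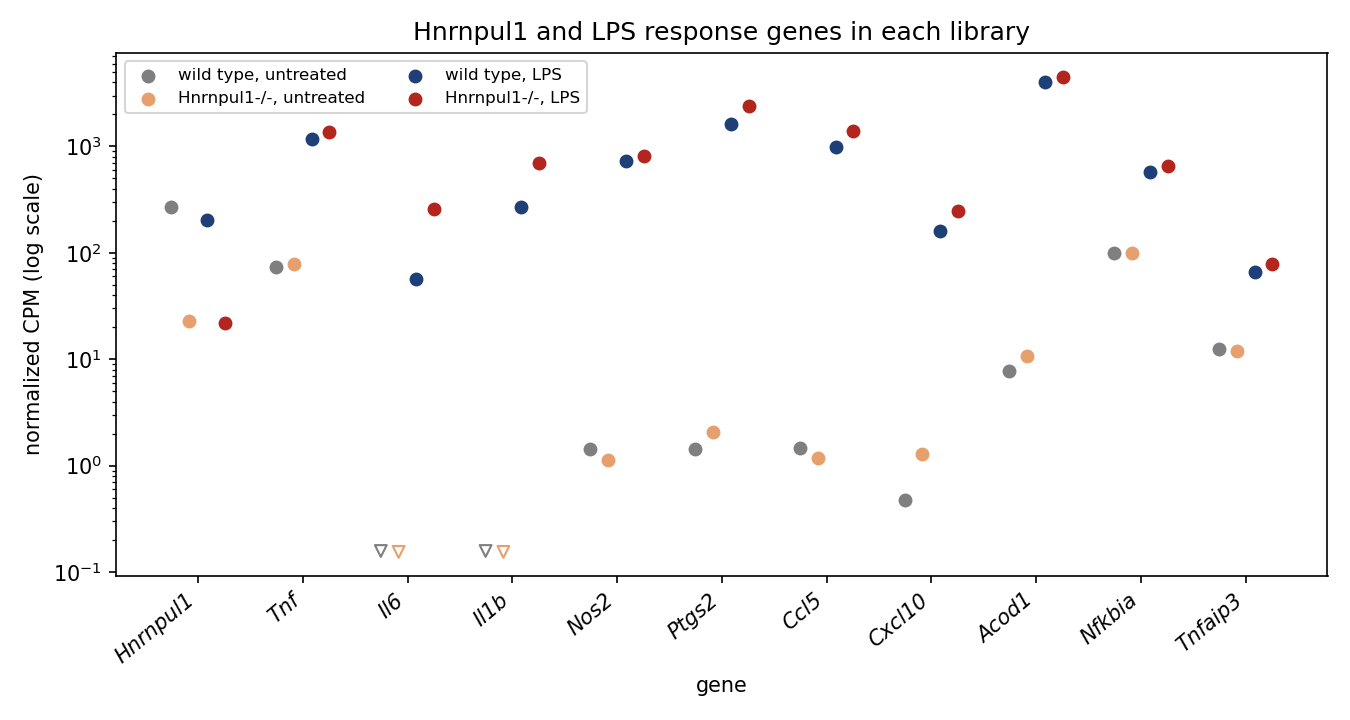
Normalized CPM (log axis) of Hnrnpul1 and 10 LPS response genes in each of the 4 libraries, 1 point per library; open triangles mark 0 reads, drawn at the level of 3 reads. Hnrnpul1 stood at 23.1 and 21.7 CPM in the knockout libraries against 268 and 203 CPM in wild type, and Il6 at 258 CPM in LPS-treated knockout against 57.1 CPM in LPS-treated wild type.

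In untreated cells, genotype separated few genes by 2-fold, and most genes of the interferon response had ratios above 0. The type I interferon list had a median log2 ratio of 0.56, knockout to wild type, above all 10000 matched random lists, with 37 of 44 members above 0 and 4 called higher. Ifit3 had 2 reads in wild type and 16 in knockout (log2 ratio 2.97, 0.88 to 6.14), and Rsad2, an antiviral enzyme, was higher by 1.29 (0.19 to 2.52). Slfn5 went from 0 reads to 13, a log2 ratio of 2.09 against the floor of 3 counts, with a lower counting limit of 1.58. The macrophage activation list had a median of 0.32, also above all random lists and under the same limit, with no member called. H2-Eb1, a class II histocompatibility gene outside the interferon list, was higher by 3.46 (2.15 to 5.14). Under the filter on low counts, H2-Aa and H2-Ab1 had 54 and 24 reads in untreated knockout and 0 in untreated wild type. Ciita had 24 reads against 3, and H2-DMb1 3 against 2. With LPS, H2-Aa and H2-Ab1 had 8 reads each in knockout and 0 in wild type.

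Genes called untreated and not called under LPS included Ifit3, Slpi (2.41), Stx11 (2.39, 0.58 to 4.81) and Msr1, a scavenger receptor (1.97), higher in knockout. Those lower were Pecam1 (-1.60), Dock4 (-1.39), Ehd2 (-1.31) and Ms4a6c (-1.24). The interaction was called for these genes except Ehd2 (0.55, -0.41 to 1.51), and Slpi was just under the size rule with LPS (0.94, 0.86 to 1.02). DNA replication genes had a median of 0.11 with 30 of 33 above 0 and none called. Glycolysis and hypoxia genes had a median of -0.10 and a percentile of 0.025, with Adm called lower (-1.11, -1.72 to -0.52). Double-strand break repair genes had a median of 0.07 at percentile 98.3, with Xrcc5, a subunit of the Ku end-binding complex, called higher (1.19, 0.80 to 1.59). The LXR and lipid export list had a median of -0.11 at the 0.43rd percentile with no member called. TLR4 pathway genes had a median of 0.07 at percentile 98.8 and no call. The alternative activation list had a median of -0.15 at percentile 1.22, with Msr1 its called member. This median was the ratio of Il1rn, on 37 reads in untreated wild type and 34 in untreated knockout (-0.87 to 0.56). The list no longer stood apart with a mean CPM of at least 10 (percentile 21.9) or with members of at least 10 reads on average (23.6). Cytokines and chemokines had a median of 0.03 at percentile 89.0, with Cxcl10 higher (1.45, 0.30 to 2.73) and Ccl2 lower (-1.16, -1.68 to -0.65). In all 134 genes were higher and 100 lower; in simulated libraries 42 unchanged genes were called at an assumed biological coefficient of variation of 0.1 and 304 at 0.2. Of genes with a mean CPM of at least 10, 97.7% lay within 1.5-fold.

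Under LPS, the cytokine and chemokine list was higher in knockout, with a median log2 ratio of 0.57 and 21 of 24 members above 0. Of these, 6 were called higher and 0 lower. Csf2, the granulocyte-macrophage colony-stimulating factor, was at 4.43 CPM in wild type and 25.2 CPM in knockout (2.51, 2.14 to 2.90). Lif was higher by 2.33 (2.14 to 2.51), Il6 by 2.18 (2.07 to 2.28), Lta by 2.04 (1.85 to 2.25), Il1b by 1.37 (1.32 to 1.42) and Il1a by 1.09 (1.04 to 1.15). Tnf had a ratio of 0.20 (0.17 to 0.23) and Nos2 0.15 (0.11 to 0.18), both under the size rule.

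NF-kB feedback genes had a median of 0.26 above all random lists, with 20 of 24 above 0 and none called; Nfkb2 had a ratio of 0.86 (0.79 to 0.93). The macrophage activation list (median 0.17, percentile 99.9) had 5 members higher, among them Edn1 (1.74), Fpr2 (1.70), Cd86 (1.19) and Cd80 (1.17), and 1 lower. NRF2 target genes had a median of -0.24, below all random lists, with 2 of 21 members above 0 and Hmox1 called lower (-1.12, -1.14 to -1.09). DNA replication (0.27) and mitosis genes (0.22) had medians above all random lists with none called. The macrophage identity list had a median of -0.13 at percentile 0.09, with Lyz2, lysozyme, lower (-1.42, -1.45 to -1.40). Glycolysis and hypoxia genes had a median of -0.08 at percentile 0.87 with none called. The interferon list had a median of -0.03 at the 8.97th percentile, with Slfn5 called higher (1.67, 1.54 to 1.79) as it was untreated. Negative regulators of cytokine signalling had a median of 0.17 at percentile 99.9, with Cish (2.21) and Il1rn (1.52) higher; with a mean CPM of at least 10 the median was -0.04.

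Called under LPS and not called untreated were Cytip (4.52, from 1 read to 24; 1.90 to 9.88), Csf2, Lif and Aqp9, a water and glycerol channel (2.22), higher, and Angptl2 (-3.32), S1pr1 (-2.33), Gem (-2.30) and Cldn11 (-1.996), lower. The interaction was not called for Csf2 (0.54, -2.65 to 3.72), and for Lif no value is given, since Lif had 1 and 0 reads untreated. Angptl2 and Gem had untreated ratios of -0.99 (-1.19 to -0.80) and -0.94 (-1.42 to -0.47). In all 193 genes were higher and 213 lower, where simulation called 54 unchanged genes at an assumed biological coefficient of variation of 0.1 and 315 at 0.2. Of genes with a mean CPM of at least 10, 95.4% lay within 1.5-fold.

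**Figure D2:**
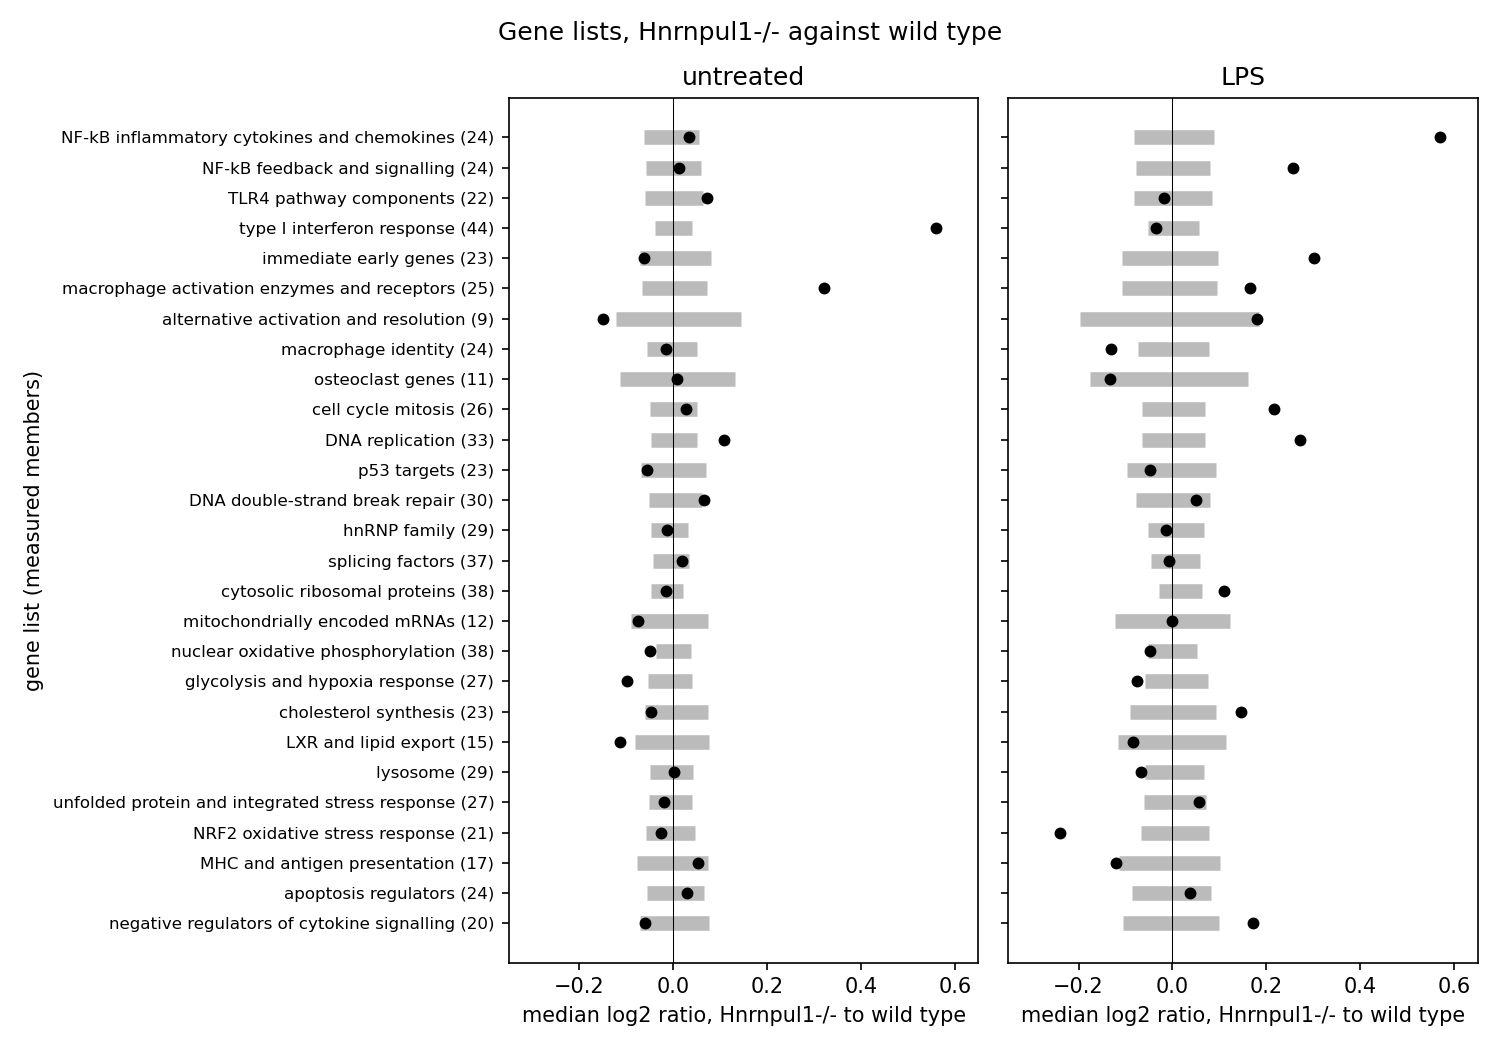
Median log2 ratio, knockout to wild type, of each of 27 gene lists (black points), untreated at left and LPS-treated at right. Grey bars give the central 95% of random lists matched on mean expression over the 4 libraries, and the number of measured members stands in brackets. The interferon list lay at 0.56 untreated and the cytokine and chemokine list at 0.57 under LPS.

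A group of genes differed between genotypes in the same direction whether or not LPS was given. Egr1, an immediate early transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), had 0 reads in both wild-type libraries, 443 in untreated knockout and 1530 in LPS-treated knockout. Against the floor of 3 counts, Egr1 was 145-fold and 486-fold higher, with lower counting limits of log2 6.87 and 8.63. Pcdhgc3, a protocadherin, also had 0 reads in both wild-type libraries and 228 and 294 in knockout. Against the same floor it was 74.5-fold and 93.4-fold higher, with lower counting limits of log2 5.91 and 6.24. Its exons are partly shared with other genes of its cluster. Cysltr1, a leukotriene receptor, was higher by 6.23 (5.00 to 7.86) untreated and 7.84 (5.35 to 13.15) under LPS, and Antxr1, an anthrax toxin receptor, was lower by -5.71 (-7.34 to -4.46) and -5.45 (-6.91 to -4.31).

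Gypc (7.56, 5.07 to 12.88, and 5.12), Cd5 (1.83 and 3.86) and Acap1 (2.59 and 1.97) were higher in knockout in both treatments. Besides Hnrnpul1 itself, Rgs16, a regulator of G protein signalling (-2.31 and -1.75), Npl (-1.52 and -2.34), Ctsh, cathepsin H (-1.64 and -2.13), and Rab15 (-1.71 and -1.85) were lower. In all, 40 genes were higher and 38 lower in both treatments, where independent lists would share 2.22 and 1.83; 7 were called in opposite directions. The additive model with edgeR's quasi-likelihood test gave 223 genes at an adjusted p threshold of 0.05, of which 58 were at least 2-fold higher and 29 at least 2-fold lower in knockout; these held 28 of the 40 and 19 of the 38. Across genes, the ratios of the 2 treatments had a Pearson correlation of 0.43.

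**Figure D3:**
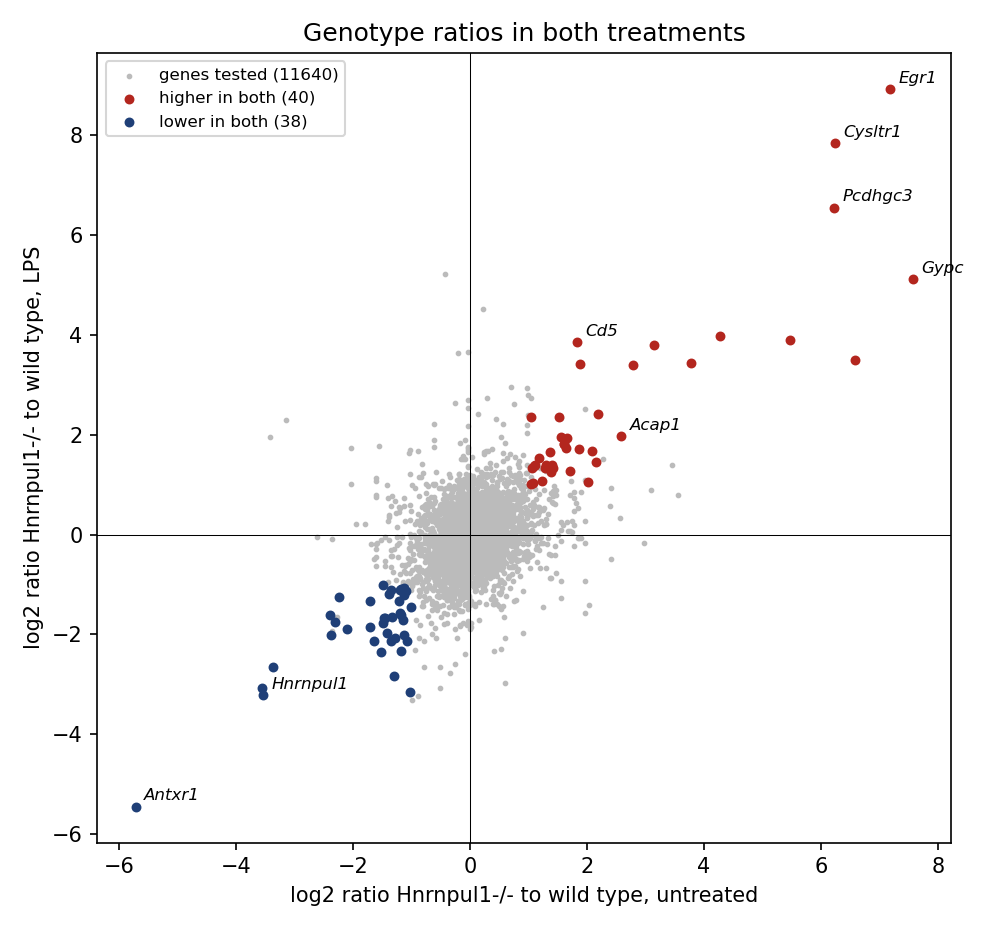
Log2 ratio of knockout to wild type in untreated (x axis) and LPS-treated cells (y axis) for each of 11640 genes, 1 grey point per gene; red and blue points are the 40 genes higher and the 38 lower in both. Egr1, with 0 reads in wild type, is drawn at its ratios of 7.18 and 8.93 against the floor of 3 counts. Its lower counting limits were 6.87 and 8.63. Antxr1 lies at -5.71 and -5.45.

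Over the genes most changed by LPS, neither genotype had the larger response on balance, while single genes and gene lists differed in both directions. Of the 500 genes with the highest mean LPS ratio, 255 (51.0%, exact binomial interval 46.5 to 55.5%, which treats genes as independent although they are not) had the larger response in knockout, and the median difference was 0.01 (quartiles -0.49 and 0.47), with 22 interaction calls higher and 23 lower. Of the 500 lowest, 262 (52.4%, 47.9 to 56.9%) had the more negative ratio in knockout. Their median difference was -0.03, with 15 interaction calls higher and 32 lower. Interaction calls leaned lower over all genes as well (138 higher and 214 lower), so this lean was not read as particular to genes lowered by LPS. With the deposited FPKM, called without a counting interval on another set of genes, the lean over all genes was absent (132 and 124). The interferon list had a median interaction of -0.53, below all random lists, with 5 members lower and 0 higher, among them Ifit3 (-3.14, -5.27 to -1.02), Ifi44 (-1.26, -1.50 to -1.01) and Oas2 (-1.23, -1.45 to -1.01); since the interaction is the difference of both genotype ratios, this restates the higher untreated level. The cytokine list had a median interaction of 0.42, above all random lists, which likewise follows from its genotype ratios. Its called members were Il23a (1.37), Il27 and Ccl2 (1.10). Of the 6 called higher in knockout under LPS, Csf2, Lta and Il1a were not called in the interaction, and Il6, Il1b and Lif had 0 reads in an untreated library, so that no value is given for them. In all 7 of 27 lists lay above and 6 below the central 95% of random lists in the interaction. The 1.35 given by chance treats genes of a list as independent although they are not. Nor does the matching of random lists allow for members with few untreated reads. The others above were NF-kB feedback (0.27), immediate early (0.40), mitosis (0.16), DNA replication (0.12), ribosomal protein (0.12) and cholesterol synthesis genes (0.19), and the others below were macrophage identity (-0.17), osteoclast (-0.21), lysosome (-0.12), NRF2 target (-0.25) and antigen presentation genes (-0.18).

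Single genes with a larger LPS ratio in knockout were Cytip (4.30, 1.40 to 7.19), Aqp9 (2.83, 0.23 to 5.43), Il27 (2.14, 0.65 to 3.63), Cd5 (2.03), Il1rn, the interleukin-1 receptor antagonist (1.67, 0.99 to 2.35), and Tsku (1.36). Those with a smaller or more negative one were Ifit3, S1pr1 (-2.74), Rpl30 (-2.70), Angptl2 (-2.33), Stx11 (-1.82, -3.62 to -0.02) and Jag1, a Notch ligand (-1.76, -2.11 to -1.42). Rpl30 has many processed pseudogenes and its count is uncertain. In all, 138 genes had a higher and 214 a lower LPS ratio in knockout (39.2% higher). With the deposited FPKM, called without a counting interval on another set of genes, these were 132 and 124 (51.6%). In simulation 120 unchanged genes were called at an assumed biological coefficient of variation of 0.1 and 1188 at 0.2. The simulated libraries held no LPS effect, so these numbers do not cover genes that LPS leaves with few reads in some libraries.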

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

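The last 2 of the 3 tests of carry-over and the 2 tests of neighbours that kept called genes were chosen only after the result was seen, as was leaving out Spp1 or Gypc; the other tests were set beforehand. No group held the 4 libraries needed to look for outliers. Genes called in opposite directions in the 2 genotypes with LPS, or in the 2 treatments by genotype, are given here by the difference of their log2 ratios, the interaction. It carries a counting interval (3.14 to 7.61 for Nr4a1), but against the spread between replicates these differences were not tested. Apold1 (5.44) and Nr4a1 (5.37) were lower in knockout untreated and higher under LPS, on 2 to 65 reads, as were Gm44154 (3.77), Gm6257 (3.32) and 1700047I17Rik2 (2.67). Rpl30 (-2.70) and Gm20784 (-3.46) went the opposite way. For LPS itself, Gm6257 (3.32), Gm11007 (-2.90) and Gm38357 (-2.03) were called in opposite directions in the 2 genotypes.

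Egr1 and Pcdhgc3 had 0 reads in both wild-type libraries and over 100 in both knockout libraries, and 78 genes in all differed the same way in both treatments. The 16 measured genes within 250 kb of Egr1 and Pcdhgc3 had a median log2 ratio of 0.0887, which argues against a deletion reaching the neighbours in the wild-type cells; a deletion of these genes alone stays open. Of the 78 genes, 15.4% had another of the same direction within 1 Mb, exactly the upper end of the central 95% of 1000 random sets, which decides nothing, and nor does the median signed ratio of 0.00692 over 505 neighbours, since called genes were left out of it. With called genes kept, the median was 0.00902 (quartiles -0.09 and 0.15) over 517 neighbours within 250 kb, and 0.0325 (-0.07 and 0.30) over the 102 neighbours of the 12 genes near each other, which argues against gain or loss of segments reaching most genes over that distance. What stays open is smaller changes, the genotype itself and the history of the cells: the labels name 1 line per genotype, so a difference between lines that arose in culture or during cloning is not separated from an effect of Hnrnpul1 by these libraries.

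The cytokine and chemokine list was higher in knockout under LPS. Among lists drawn from the 500 genes most raised by LPS, its median lay at percentile 99.9, which argues against a shift of every LPS-induced gene by the same factor. These 500 genes had median LPS log2 ratios of 3.59 in wild type and 3.57 in knockout, against 6.40 and 7.15 for the list. A difference that grows with the size of the LPS response was thus not tested. Its percentile of 100 under both DESeq2 and total-count scaling tests nothing, since a scaling factor moves the list and its random lists alike. An effect of Hnrnpul1, a difference between lines and a difference in the timing or dose reaching 1 culture may each account for it, and the 4 libraries do not separate them.

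The interferon list was higher in untreated knockout; its percentile of 100 under DESeq2 and total-count scaling was fixed in the same way and tests nothing. RNA or reads carried over from an LPS-treated library could give this, and 3 tests of it were run: the planned one met its bound in favour of carry-over (20 abundant LPS-induced genes held 0.653 of the predicted excess, with Spp1 giving 54.0% of it and 0.362 left without Spp1), and so did the next (125 near-silent genes held 0.771 of the predicted reads, with Gypc, a gene higher in knockout in both treatments, giving 52.0% and 0.372 left without Gypc). The last, chosen after single genes had been inspected, asked for proportion to the LPS level. Csf3, Il1b, Il1a, Ifi202b and Il6 held 7 reads in untreated knockout, with an exact upper limit of 14.4, where 309 were predicted. This ratio of 0.0227 argues against carry-over as the whole source. For these 5 genes, the upper limit bounds any share carried over in proportion to the LPS level. The first 2 tests each met their bound through 1 gene. The values without it lie between their bounds, so those 2 tests neither show nor exclude a smaller share from carry-over. A higher resting interferon response in knockout is the biological candidate, untested and not separable from the history of the lines.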

How the results depend on the processing

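Restricting lists to members with at least 10 reads on average was chosen after seeing the data. No paired analysis was possible because each group held 1 library, so that no replicates pair across groups, and for the same reason no library could be left out in turn; the additive model sets each factor against the other with 1 residual degree of freedom. Under DESeq2 size factors and thinning to equal depth, all 14 counts of called genes stayed within 1.5 times, as did the 4 counts of genes changed in both pairs under the additive edgeR test. Hnrnpul1 remained at 8.54 to 8.69% untreated and 10.7 to 10.8% under LPS in every alternative run, and the shares of LPS genes with the larger response in knockout stayed within their intervals. In the order LPS in wild type, LPS in knockout, genotype untreated, genotype under LPS, interaction, LPS in both genotypes and genotype in both treatments, each as higher and lower, the 1.5-fold rule gave 2202 and 2230, 2247 and 2448, 316 and 253, 463 and 524, 307 and 449, 1856 and 1870, 105 and 112, as a looser rule must give more. Total counts gave 1904, 2156 and 1583 genes lower with LPS in wild type, knockout and both, from the shift of the median. Without a filter on low counts more genes were tested, and the genotype counts were 303 and 262 untreated and 384 and 402 under LPS, and the interaction 245 and 356. With a mean CPM of at least 10, fewer genes were tested: 691, 793 and 621 were lower with LPS in wild type, knockout and both, the genotype counts were 27 and 16, 42 and 60, and 8 and 8 in both treatments, and the interaction 21 and 42. With the whole interval beyond 2-fold, 728, 863 and 627 were lower with LPS, the genotype counts were 28 and 20, 65 and 56, and 15 and 11, and the interaction 12 and 27. The deposited FPKM, called without a counting interval on another set of genes, gave 681, 766 and 550 lower with LPS. Their genotype counts were 61 and 46, 103 and 94, and 14 and 11. In the interaction 132 were higher and 124 lower, so that the excess of lower genes was absent, and the cause was not tested. Among protein-coding genes alone the interaction had 86 higher, with fewer genes tested. The list of negative regulators of cytokine signalling turned from a median of 0.17 under LPS (percentile 99.9, knockout to wild type) to -0.04 (percentile 19.7) with a mean CPM of at least 10; the cause was not tested. The alternative activation list lost its untreated call with that filter (percentile 21.9) and with members of at least 10 reads on average (23.6). List percentiles were run under thinning, that filter and that restriction (genotype comparisons alone), where the other list calls kept their side and 3 lists gained a call in 1 setting each. They were also run under DESeq2 and total-count scaling, which cannot move them, and not under the other alternatives. Named genes apart from Hnrnpul1 were also run, without those named only as list members. Of their log2 ratios, 204 of 204 stayed within their intervals under DESeq2 size factors and under thinning, and 31 of 204 moved under total counts, without a change of sign of a called ratio. Depth limits the ratios of genes with few reads, and a count of 0 allows a bound alone.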

Other observations

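Further lists described the genotype comparison. Immediate early genes had a median log2 ratio, knockout to wild type, of -0.06 untreated and 0.30 under LPS (above all random lists); besides Egr1, Fos was lower untreated (-1.10, -1.49 to -0.71), Dusp2 higher (1.02, 0.89 to 1.16) and Egr3 lower under LPS (-1.77, -2.84 to -0.81). Cytosolic ribosomal protein genes had a median of 0.11 under LPS with 37 of 38 above 0, none called, and Rps27a at 0.87. Cholesterol synthesis genes had a median of 0.15 under LPS at percentile 99.9 with none called. Lysosome genes (-0.07, percentile 1.46) included Ctsh, and antigen presentation genes (-0.12, percentile 1.92) included H2-DMa, lower by -1.03 (-1.96 to -0.14). Osteoclast genes had a median of -0.13 under LPS (percentile 5.86), with Acp5 lower in both treatments (-1.21 and -1.32). Genes of nuclear oxidative phosphorylation had medians of -0.05 in both treatments, at percentiles 0.63 and 3.19. Splicing factors (0.02 and -0.01), the hnRNP family (-0.01 and -0.01), p53 targets (-0.06 and -0.05), apoptosis regulators (0.03 and 0.04), stress response genes (-0.02 and 0.06) and mitochondrially encoded mRNAs (-0.08 untreated) lay inside the central 95% of random lists in both treatments.

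With LPS, in wild type and knockout, immediate early genes had medians of 1.60 and 2.06, alternative activation genes 3.18 and 1.74, negative regulators of cytokine signalling 2.78 and 2.85, and apoptosis regulators 0.47 and 0.75, each above the central 95% of random lists, as were p53 targets (0.33 in both). Only 9 of 20 alternative activation genes were measured, of which 7 were called higher and 1 lower in each genotype. Mrc1, Chil3, Retnla and Cd163 of that list had 0 to 2 reads in each library. Genes of the hnRNP family (-0.17 and -0.08), splicing factors (-0.09 and -0.06) and nuclear oxidative phosphorylation (-0.16 and -0.23) lay below it with none called. Macrophage identity genes (0.50 and 0.39) lay above it in wild type only. TLR4 pathway genes (0.25 and 0.24), ribosomal protein genes (0.13 and 0.25), mitochondrially encoded mRNAs (0.19 and 0.21), LXR and lipid export genes (0.15 and 0.17), lysosome genes (0.29 and 0.20) and osteoclast genes (0.42 and -0.10) lay inside it in both.

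Most markers of other cell types were unmeasured: the measured ones were 2 of 15 for T lymphocytes (Cd28 and Lck), 2 of 14 for B lymphocytes (Ighm and Pax5), 1 of 15 for fibroblasts and endothelium (Pecam1) and 0 of 15 for neutrophils and mast cells, 0 of 12 for epithelium and 0 of 11 for erythroid cells. The 2 B lymphocyte markers reached up to 278 CPM. In each genotype 1 of them was called higher with LPS, and under LPS 1 was called lower in knockout. Of 43 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 1 was measured (Hist1h1c, lower with LPS by -1.43 and -1.52).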
